A study of Homo sapiens with 26 samples.

How the data were processed

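The deposited table held counts per gene for the 8 RNA libraries, which the authors made from total RNA of MCF7 cells. Per the labels, cells were grown in RPMI medium with fetal bovine serum and the RNA was extracted with RNAzol. The submitters' notes name Trim Galore 0.4.4, Bowtie2 2.3.4.1, HTSeq 0.9.1, MACS2 2.1.1.20160309, deepTools 3.1.1 and the genome hg19, without saying which step or data type each served. The RNA aligner, the annotation release, the strand setting and the rule for reads with several matches were not given in the sources used here. The 18 ChIP-seq samples of the series were not analysed. The aim stated for the series was to compare binding of the estrogen receptor and γH2AX, and the transcriptome, between BRCA1-knockdown and control MCF7 cells with and without E2.

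Counts were between 63825141 and 69090417 per library over 57773 genes, of which 22230 had 0 counts in every library. Ensembl gene IDs were given symbols from a table of gene names, and 39538 IDs matched. A RefSeq table for GRCh38.p14 served only to find older symbols. Symbols without a match in the count table were TXNIP, UHRF1, BOP1, HIST1H3B, HIST1H3H, HIST2H2AA3 and NEFL.

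Genes were filtered with filterByExpr of edgeR at a minimum count of 10, which left 20592. Libraries were scaled with TMM factors, and a model with 1 mean per group was fitted with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 (biological coefficient of variation 0.0744, 4 residual degrees of freedom, 13.2 prior degrees of freedom). Tests were E2 against ethanol in control and in shBRCA1 cells, shBRCA1 against control cells in ethanol and in E2, and the difference between both E2 effects. P-values were adjusted by Benjamini-Hochberg over all genes tested within a comparison, and a gene was called at an adjusted p under 0.05. Levels are CPM with TMM factors, as mean and SD of 2 libraries. The principal component analysis used log2 CPM with a prior count of 2, and the chi-square between the libraries of a group used genes with at least 20 counts. For a gene with 0 counts in a group a floor of 3 counts over the group was used. Intervals and floors cover counting error only.

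Before the data were examined, 23 gene lists were fixed: estrogen-induced, estrogen-repressed, luminal, basal and mesenchymal, DNA replication, mitosis, homologous recombination, end joining and ATM, R-loops and transcription-linked damage, p53 targets, interferon-stimulated, NF-κB, unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, ribosome biogenesis, immediate-early, ribosomal protein, replication histone and mitochondrially encoded genes, and markers of fibroblasts, blood cells and a packaging line. The 20 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the fixed lists of the 4 pairwise comparisons together and over those of the difference apart. Camera with an estimated correlation and fry were run beside it. The estimated setting also lost a call where the estimated correlation lay below the preset, so such a loss need not come from correlation between genes. Fry called 57 list tests of the pairwise comparisons, against 51 with camera, and 11 of the difference, against 14. Another 7 lists were chosen after the results were seen: antigen presentation, interferon ligands, epidermal differentiation, basal keratinocyte, TGF-β target, neuronal and MHC class II genes. They were adjusted in the same way, apart from the fixed lists.

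Genes were named by a fixed rule. BRCA1 was named in every comparison. The 7 largest rises and the 7 largest falls were named among called genes with a mean of at least 5 CPM in the higher group, no overlap between the libraries of both groups and a symbol that is not a clone name. For the difference between E2 effects the same rule held without the overlap condition. From each list up to 2 rising and 2 falling members with the smallest p were named, or the member with the smallest p if none was called. GREB1, TFF1, PGR, MYC and ESR1 were named in the E2 comparisons.

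Results were set beside 21 other settings: an adjusted p under 0.01, an absolute log2 fold change of at least 1, estimated correlation, fry, RLE, upper-quartile or no scaling factors, DESeq2 1.42.0, limma-voom, no filter on counts, a filter of 1 CPM in 2 libraries, a block for replicate number, each of the 8 libraries left out, and fits to the 2 groups compared only. The code was tested on simulated data with 50 genes changed at each of 4 fold sizes and a list of 20 further genes raised 1.5-fold. In the simulated E2 comparison of control cells it found 36% of genes changed 1.25-fold, 70% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 11 unchanged genes among 179 calls, which include genes of the raised list. For the difference between E2 effects it found 10%, 52%, 80% and 100%, with 5 unchanged genes among 138 calls. Simulated comparisons without any change gave 0 calls in the edgeR test, and 0 of 20 unchanged lists were called by camera. These checks test the code and give no error rates for the correlated genes and unequal group noise of these data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and figures.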

Results

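RNA was sequenced from MCF7, an established estrogen receptor-positive human breast cancer cell line, in a design that crossed a BRCA1 knockdown with estrogen treatment. Control cells, labelled shEV, and cells with an shRNA against BRCA1, labelled shBRCA1, were each treated for 12 h with ethanol, the vehicle, or with 10 nM of E2 (estradiol, the main natural ligand of the estrogen receptor). BRCA1 encodes a tumor suppressor that acts in the repair of DNA double-strand breaks by homologous recombination. Each of the 4 groups held 2 libraries. After the filter on low counts 20592 genes were left. The 18 ChIP-seq samples, not analysed here, are labelled as estrogen receptor, γH2AX or input. Some for γH2AX had DRB, a drug that blocks transcription. The labels do not say whether the 2 libraries of a group came from separate cultures, so the spread behind the p-values may be technical. That spread was estimated per gene from all 4 groups together, so a p-value does not measure the spread of the compared groups alone.

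The libraries fell into 4 separate pairs in a principal component analysis. On the first component, with 36.9% of the variance, the E2 libraries lay above the ethanol libraries of the same cells, and the shBRCA1 libraries lay below the control libraries of the same treatment. Within a pair, log2 CPM values correlated across genes with a Pearson r between 0.985 and 0.988. Pairs differed by more than sampling noise, which alone gives a mean chi-square of about 1 per gene. That mean was 4.24 in control cells in ethanol, 10.8 in control cells with E2, 9.28 in shBRCA1 cells in ethanol and 26.2 in shBRCA1 cells with E2. Transcripts encoded by the mitochondrial genome took 6.64% and 6.47% of the counts in control cells in ethanol, 5.45% and 5.34% in control cells with E2, 7.16% and 7.39% in shBRCA1 cells in ethanol, and 6.52% and 7.59% in shBRCA1 cells with E2.

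The targeted gene, BRCA1 (ENSG00000012048), had 3698 and 3866 counts in the control libraries in ethanol and 2436 and 2806 counts in the shBRCA1 libraries in ethanol. With E2 it had 2918 and 2860 counts in control libraries and 2375 and 2421 counts in shBRCA1 libraries. As CPM (mean ± SD, n = 2), these were 56.8 ± 2.096, 39.4 ± 2.04, 45.2 ± 0.609 and 37.4 ± 2.08 in the same order of groups. BRCA1 was lower in shBRCA1 cells in ethanol, at 0.694 times the control level (log2 fold change −0.53, SE 0.0725, adjusted p = 6.5e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With E2 it stood at 0.826 times the control level (log2 fold change −0.28, SE 0.0731, edgeR adjusted p = 0.0117). That call was lost without the first or second control E2 library, at log2 fold changes of −0.26 and −0.29. Fits of this kind leave 1 library in a group, so a lost call can come from lost replication alone. E2 itself lowered BRCA1 in control cells (log2 fold change −0.33, SE 0.0723, edgeR adjusted p = 0.00266), which was lost without the second control ethanol library (edgeR adjusted p = 0.0598). In shBRCA1 cells the E2 effect on BRCA1 was −0.08 (edgeR adjusted p = 0.552), and the difference between both E2 effects was not called (0.25, SE 0.103, edgeR adjusted p = 0.217).

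**Figure D1:**
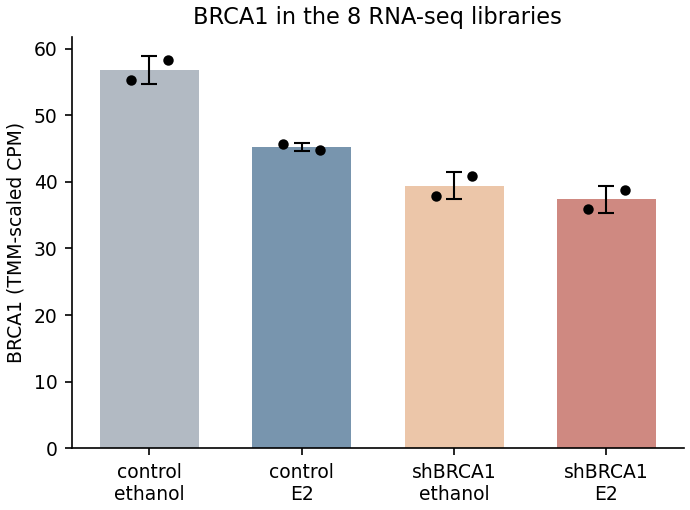
BRCA1 level in CPM in the 4 groups; bars are group means, error bars are SDs (n = 2) and points are the 2 libraries. The shBRCA1 groups stood at 39.4 and 37.4 CPM in ethanol and E2, and the control groups at 56.8 and 45.2 CPM.

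The first comparison asked how control cells responded to E2. Known estrogen targets rose. GREB1 (ENSG00000196208) went from 763 ± 8.99 to 2387 ± 189 CPM (mean ± SD, n = 2; log2 fold change 1.65, SE 0.0756, edgeR adjusted p = 2.37e-11). TFF1 (ENSG00000160182) rose from 1037 ± 13.6 to 2534 ± 172 CPM (log2 fold change 1.29, SE 0.0788). PGR, the progesterone receptor gene, rose by a log2 fold change of 0.68 and MYC by 0.84, while ESR1 (ENSG00000091831), which encodes the estrogen receptor itself, fell from 336 ± 3.45 to 164 ± 4.17 CPM (log2 fold change −1.04). Antiviral and inflammatory genes rose with them: OAS2 (ENSG00000111335) went from 35.6 ± 1.78 to 323 ± 6.62 CPM (log2 fold change 3.18, SE 0.0727). TNFAIP3 (ENSG00000118503) rose from 23.8 ± 1.10 to 106 ± 1.98 CPM (log2 fold change 2.15, SE 0.0834).

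Among estrogen-induced genes, 28 of 40 rose and 4 fell with E2 in control cells (30 and 4 adjusted over the list alone; camera adjusted p = 5.79e-15). EGR3 rose with a log2 fold change of 2.52 and HSPB8 with 1.93, whereas AGR2 (−0.87) and ELOVL2 (−0.35) fell. All 18 immediate-early genes rose (18 adjusted over the list alone; camera adjusted p = 3.37e-21), as did 27 of 28 interferon-stimulated genes (27 adjusted over the list alone; camera adjusted p = 5.63e-46), among them IFIT3 (log2 fold change 3.09). Of 13 NF-κB target and inflammatory genes 10 rose (12 adjusted over the list alone; camera adjusted p = 5.77e-14), including NFKBIA (log2 fold change 1.21). Hypoxia and glycolysis genes rose in 17 of 19 cases (17 adjusted over the list alone; camera adjusted p = 9.74e-14), with VEGFA at a log2 fold change of 1.18 and SLC2A1 at 0.88. Further lists that moved upward were p53 targets (12 of 22 rose and 1 fell, the same adjusted over the list alone; camera adjusted p = 1.58e-06), led by CDKN1A (1.47) and GADD45A (1.57), and unfolded protein response genes (15 of 19 rose and 1 fell, the same adjusted over the list alone; camera adjusted p = 1.26e-08). Cholesterol synthesis genes (14 of 21 rose, 14 adjusted over the list alone; camera adjusted p = 1.65e-07) and basal and mesenchymal genes (9 of 13 rose, 9 adjusted over the list alone; camera adjusted p = 3.49e-07) moved upward too. In the last list TP63 went from 5.56 ± 0.935 to 46.8 ± 0.0672 CPM and KRT17 had a log2 fold change of 4.03. Without the second control ethanol or the first control E2 library 9 cholesterol synthesis genes rose. The falling estrogen-induced genes were 2 without any 1 of the 4 control libraries, and that of the unfolded protein response 0.

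Genes of DNA replication moved the other way in control cells: 19 of 29 fell with E2 (20 adjusted over the list alone), among them RRM2 (log2 fold change −0.41) and GINS2 (−0.50), with a camera adjusted p = 1.76e-10 that became an adjusted p = 0.0923 with an estimated correlation. In the mitosis list 6 of 25 genes fell (6 adjusted over the list alone), including BIRC5 (−0.54), with a camera adjusted p = 0.00155 (adjusted p = 0.378 with an estimated correlation). That number of falling mitosis genes was 12 with upper-quartile factors and 17 with library sizes alone. Homologous recombination genes fell in 8 of 26 cases (11 fell and 1 rose adjusted over the list alone), FANCA (−0.49) and FANCD2 (−0.34) among them, with a camera adjusted p = 0.00185 (adjusted p = 0.131 with an estimated correlation). Of 13 genes encoded by the mitochondrial genome 8 fell (8 adjusted over the list alone; camera adjusted p = 2.31e-04, adjusted p = 0.218 with an estimated correlation), which goes with the lower mitochondrial share of the counts in these libraries, 5.45% and 5.34% against 6.64% and 6.47%. The number of falling mitosis genes was 2 without the first control ethanol library, 3 without the second control E2 library, and 11 and 10 without the first and second shBRCA1 E2 library. That of homologous recombination genes was 4 and 3 without the first and second control ethanol library. That of mitochondrially encoded genes was 1 and 2 without the first and second control ethanol library and 2 without the second control E2 library. In the ribosomal protein list 2 of 28 genes fell (1 adjusted over the list alone; camera adjusted p = 0.0436, adjusted p = 0.687 with an estimated correlation, fry adjusted p = 0.465). It had 8 falling genes with upper-quartile factors and 10 with library sizes alone, and without the second control E2 library that list's direction turned (camera adjusted p = 0.745). It also lost its call without the first control ethanol library (0.114), the second (0.0672), or the first (0.0504) or second (0.0542) shBRCA1 ethanol library, and with RLE size factors (0.0673). Its falling genes were 1 without the first or second control ethanol or the second control E2 library, 4 without the first control E2 library and 5 without either shBRCA1 E2 library. Lists without a call were estrogen-repressed genes (5 of 15 rose and 5 fell), and luminal genes (4 of 15 rose and 6 fell). The others were end joining and ATM genes (4 of 19 rose and 4 fell), genes of R-loops and transcription-linked damage (4 of 22 rose and 1 fell), ribosome biogenesis (4 of 20 rose) and replication histones (1 of 11 fell). Adjusted over the list alone, no count in these lists changed by more than 3. Among estrogen-repressed, end joining and R-loop genes the median, mean and test did not share a sign. The 4 ribosome biogenesis calls were all lost with upper-quartile factors or library sizes alone. R-loop genes then had 2 rises and 3 falls, or 2 and 4, and replication histones 4 falls with either, so no direction can be read from these lists. Over the fits without 1 library, ribosome biogenesis had 0 to 6 rises, replication histones 0 to 4 falls, luminal genes 2 to 5 rises, and end joining and R-loop genes 2 to 4 rises.

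By size, the leading rises with E2 in control cells were genes of the epidermal surface. KRT6B (ENSG00000185479) rose 110-fold from 0.0975 ± 0.0101 to 10.97 ± 0.734 CPM, and SPRR1B rose 90.9-fold. KRT6A rose 81.5-fold, S100A7A 64.8-fold, SPRR3 61.8-fold, SPRR1A 54.7-fold and S100A7 44.0-fold. These belong to families of near-identical genes, so the split of reads among KRT6, S100A7 and SPRR members is uncertain. The leading falls were TRGC1 (log2 fold change −3.62), ASCL1 (−2.97) WNT11 (−2.45), the protocadherin gene PCDH10 (−2.19), CDH18 (−1.98), HMCN1 (−1.92) and LRFN5 (−1.89). TRGC1 lies in a T-cell receptor locus and the strand setting of the counting was not given in the sources used here, so overlapping transcripts cannot be excluded for it.

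In all, 4702 genes changed with E2 in control cells at an adjusted p under 0.05, or 22.8% of those tested, 2688 higher and 2014 lower, and 624 and 342 of them changed at least 2-fold. The higher genes were 57.2% of the calls, but 43.3% with upper-quartile factors and 39.9% with library sizes alone, so the balance of small changes depended on the scaling. Without the first control ethanol library 2786 genes were called, without the second 2718, and without the second control E2 library 3084.

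The second comparison asked the same of the shBRCA1 cells. GREB1 rose from 725 ± 44.1 to 2465 ± 222 CPM (mean ± SD, n = 2; log2 fold change 1.77, SE 0.0758, edgeR adjusted p = 1.55e-11) and TFF1 from 1364 ± 86.7 to 3507 ± 413 CPM (log2 fold change 1.36, SE 0.0789). PGR rose by a log2 fold change of 0.44 and MYC by 0.40, and ESR1 fell from 490 ± 18.8 to 220 ± 17.2 CPM (−1.16). IFI27 (ENSG00000165949) rose from 9.13 ± 0.992 to 36.1 ± 0.766 CPM (log2 fold change 1.98, SE 0.0863) and OAS2 from 3.44 ± 0.250 to 11.3 ± 0.847 CPM (log2 fold change 1.71, SE 0.0916).

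Estrogen-induced genes rose in 26 of 40 cases and fell in 7 with E2 in shBRCA1 cells (27 and 9 adjusted over the list alone; camera adjusted p = 9.48e-15), with EGR3 at a log2 fold change of 2.04 and with CALCR (−0.75) and AGR2 (−0.54) among those that fell. Of 28 interferon-stimulated genes 26 rose (27 adjusted over the list alone; camera adjusted p = 1.77e-25). Immediate-early genes rose in 9 of 18 cases (9 adjusted over the list alone; camera adjusted p = 9.75e-08), with FOS at 0.76. Hypoxia and glycolysis genes rose in 11 of 19 cases and fell in 1 (13 and 2 adjusted over the list alone; camera adjusted p = 2.37e-06), CA9 at a log2 fold change of 2.06 and VEGFA at 0.81, while HK2 (−0.37) fell. HK2 lost its call without the first shBRCA1 ethanol library (edgeR adjusted p = 0.0555), where 7 genes of this list rose and 0 fell. Basal and mesenchymal genes rose in 9 of 13 cases (9 adjusted over the list alone; camera adjusted p = 3.53e-10), with TP63 going from 3.92 ± 0.812 to 30.9 ± 1.88 CPM.

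Other lists had a call that was lost with an estimated correlation. For NF-κB genes the estimated correlation was −0.0486, below the preset 0.01, so a stronger correlation was not the reason there. Estrogen-repressed genes fell in 11 of 15 cases and rose in 2 (11 and 3 adjusted over the list alone; camera adjusted p = 5.58e-06, adjusted p = 0.121 with an estimated correlation), EFNA1 (−0.60) and ESR1 among them. Of 20 ribosome biogenesis genes 9 rose (15 adjusted over the list alone; camera adjusted p = 5.07e-07, adjusted p = 0.121 with an estimated correlation), UTP20 at 0.50 and WDR12 at 0.41. In the NF-κB list 4 of 13 genes rose (4 adjusted over the list alone; camera adjusted p = 0.00999, adjusted p = 0.121 with an estimated correlation), TNF at 0.77 and TNFAIP3 at 0.40, and the call was lost without the first shBRCA1 E2 library (camera adjusted p = 0.0634). TNFAIP3 itself lost its call without the second shBRCA1 ethanol library (edgeR adjusted p = 0.0566). Unfolded protein response genes rose in 7 of 19 cases and fell in 2 (11 and 3 adjusted over the list alone; camera adjusted p = 0.0107, adjusted p = 0.197 with an estimated correlation). In the DNA replication list 6 of 29 genes fell (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00717, adjusted p = 0.334 with an estimated correlation), a call that was lost without the second shBRCA1 ethanol library (camera adjusted p = 0.092). Luminal genes rose in 6 of 15 cases and fell in 7 (6 and 7 adjusted over the list alone; camera adjusted p = 0.0479, adjusted p = 0.279 with an estimated correlation). That call was lost without the first (0.0760) or second (0.0748) control E2 library, without the second shBRCA1 ethanol library (0.0657) and with library sizes alone (0.0541). Of 28 ribosomal protein genes 2 rose (0 adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.638 with an estimated correlation, fry adjusted p = 0.417), and the call was lost without the first shBRCA1 ethanol library (0.294) or the second shBRCA1 E2 library (0.224). Without the first and second shBRCA1 ethanol library 5 and 4 ribosome biogenesis genes rose, 2 NF-κB genes rose in either case and 3 DNA replication genes fell in either case. Falling DNA replication genes were 10 without the first shBRCA1 E2 library, and rising luminal genes 2 without the first shBRCA1 ethanol library. Rising ribosomal protein genes were 9 without the first shBRCA1 E2 library and 0 without the second, or without any 1 ethanol library of either kind of cells. Falling genes of the unfolded protein response were 0 without the second shBRCA1 ethanol library and 1 without any other ethanol or the second shBRCA1 E2 library. Lists without a call were p53 targets (5 of 22 rose and 2 fell), cholesterol synthesis (5 of 21 rose and 2 fell) and mitosis (2 of 25 rose and 2 fell). No call was made either for homologous recombination (1 of 26 fell), end joining and ATM (2 of 19 rose), R-loop genes (2 of 22 rose and 1 fell, or 2 and 2 with library sizes alone), replication histones (1 of 11 rose and 1 fell) and genes encoded by the mitochondrial genome (0 of 13 changed). Adjusted over the list alone, no count in these lists changed by more than 1. The 4 mitosis calls were all lost without the first shBRCA1 ethanol library, and 1 rise and 0 falls were left without the second or without either control ethanol library. There were 2 rises and 1 fall without either control E2 library, and 1 rise and 6 falls without the second shBRCA1 E2 library. Over the fits without 1 library, p53 targets had 2 to 5 rises, end joining and ATM genes 1 to 6 rises, and mitochondrially encoded genes 0 to 2 rises and 0 to 5 falls.

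The leading rises in shBRCA1 cells were again epidermal. KRT6A had 0 counts in both shBRCA1 ethanol libraries and 10.95 ± 0.641 CPM with E2, at least 485-fold higher against a floor of 3 counts over the group. SPRR1B had 3 counts in the ethanol libraries together, and its ratio was 702 (95% counting interval 240 to 3410). SPRR3 rose 144-fold, S100A7 125-fold, KRT6B 98.7-fold, CASP14 (ENSG00000105141) 73.8-fold and S100A7A 57.9-fold. The leading falls were TRGC1 (log2 fold change −3.18), WNT11 (−2.81), KCNJ8 (−2.53), CCNP (−2.45), ASCL1 (−2.26), PCDH19 (−2.18) and PCDH10 (−2.11). In all, 3556 genes changed with E2 in shBRCA1 cells, or 17.3% of those tested, 1794 higher and 1762 lower, and 485 and 240 of them changed at least 2-fold. Fewer were called without either shBRCA1 ethanol library, and 2452 in a fit to the 2 groups compared only.

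Across all 20592 genes the E2 effects in control and shBRCA1 cells, which share no library, correlated with a Pearson r of 0.473 and a Spearman rho of 0.386. Over the 6039 genes called in either kind of cells these were 0.723 and 0.737. The r was 0.765 over the genes left by a filter of 1 CPM in 2 libraries. Genes are not independent replicates. E2 raised 1214 genes in both kinds of cells and lowered 957 in both, where independent lists of these sizes would share 234.2 and 172.3, and 48 genes were called in opposite directions.

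**Figure D2:**
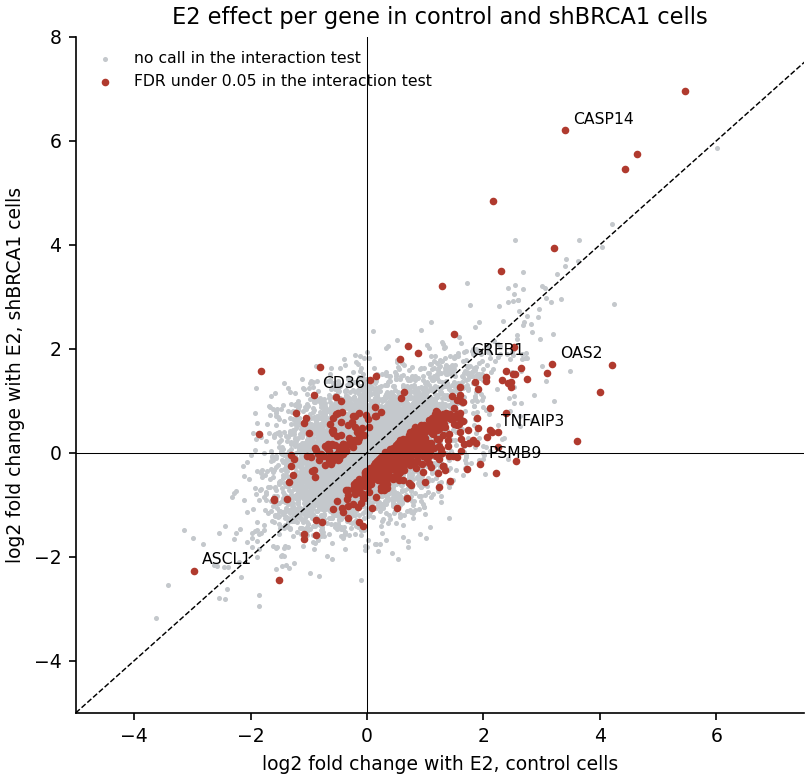
E2 effect (log2 fold change, E2 against ethanol) in control cells on the x axis and in shBRCA1 cells on the y axis; each point is 1 of 18326 genes, with 2266 genes under 0.1 CPM in a group left out, and the dashed line marks equal effects. The 666 genes in red had E2 effects that differed between the 2 kinds of cells, and most of them lie below the line.

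The third comparison asked how shBRCA1 cells differed from control cells in ethanol. Interferon-stimulated genes were lower by a wide margin. IFI27 stood at 9.13 ± 0.992 CPM in shBRCA1 cells and 148 ± 4.11 CPM in control cells (mean ± SD, n = 2; log2 fold change −4.02, SE 0.0885, edgeR adjusted p = 4.51e-15). IFIT1 (−3.64), OAS2 (−3.37), DHX58 (−3.18), OAS1 (−3.11) and DDX60 (−2.99), all antiviral genes, were with IFI27 and CA9 (−3.18) the 7 leading falls. The leading rises were SLC26A2 (ENSG00000155850) which went from 17.2 ± 1.12 to 61.3 ± 0.393 CPM (log2 fold change 1.83, SE 0.0900), NR4A3 (1.78), MYRIP (1.499), DIRAS2 (1.497), ADAMTS9 (1.44), CYP1B1 (ENSG00000138061) (1.40), and KLK10 (1.29).

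By list, 27 of 28 interferon-stimulated genes fell in shBRCA1 cells in ethanol (27 adjusted over the list alone; median log2 fold change −2.61, camera adjusted p = 1.79e-53), IFI6 going from 868 ± 17.2 to 116 ± 6.30 CPM. The IFIT and OAS genes form families of paralogs and the rule for reads with several matches was not given in the sources used here, so values of single members are less certain than those of the list. Hypoxia and glycolysis genes fell in 14 of 19 cases and rose in 2 (14 and 3 adjusted over the list alone; camera adjusted p = 1.48e-11), NDRG1 at −1.30 and SLC2A1 at 0.36. Estrogen-induced genes rose in 17 of 40 cases and fell in 4 (20 and 5 adjusted over the list alone; camera adjusted p = 1.72e-07). PGR (0.82) and NRIP1 (0.72) rose, and CA12 (−0.80) and AMIGO2 (−0.33) fell. Luminal genes rose in 8 of 15 cases and fell in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 1.36e-05, adjusted p = 0.0867 with an estimated correlation), with the E-cadherin gene CDH1 at 0.58 and the androgen receptor gene AR at 0.66. Estrogen-repressed genes rose in 9 of 15 cases and fell in 3 (9 and 3 adjusted over the list alone; camera adjusted p = 0.00228, adjusted p = 0.205 with an estimated correlation), IL1R1 at 1.248. Falling estrogen-repressed genes were 1 without the first control or first shBRCA1 ethanol library. Falling luminal genes were 0 without these or the second control ethanol library and 1 without the second shBRCA1 ethanol or first control E2 library. Rising hypoxia and glycolysis genes were 1 without any 1 ethanol library.

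Of the 13 genes encoded by the mitochondrial genome 5 rose in shBRCA1 cells in ethanol (8 adjusted over the list alone; camera adjusted p = 1.29e-05, adjusted p = 0.195 with an estimated correlation), where the mitochondrial share of the counts was 7.16% and 7.39% against 6.64% and 6.47%. R-loop genes rose in 5 of 22 cases (5 adjusted over the list alone; camera adjusted p = 0.0151, adjusted p = 0.138 with an estimated correlation), including the helicase gene DDX5 (0.41) and TOP2B (0.38), and the list's call was lost with library sizes alone (camera adjusted p = 0.0578). Of 11 replication histone genes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.0328, adjusted p = 0.199 with an estimated correlation), a call that was lost without the first control ethanol library (0.0642) or the second shBRCA1 ethanol library (0.141). All 3 histone gene calls were lost with upper-quartile factors or library sizes alone, and 0 were left without the first control ethanol or either shBRCA1 ethanol library and 1 without the second control ethanol library. Rising R-loop genes were 2 without either control ethanol or the first shBRCA1 ethanol library and 3 without the second. Rising mitochondrially encoded genes were 2 and 1 without the first and second control ethanol library, 3 and 2 without the first and second shBRCA1 ethanol library and 9 without either shBRCA1 E2 library. Lists without a call were homologous recombination (4 of 26 rose and 4 fell, BRCA1 among the latter), end joining and ATM (5 of 19 rose and 1 fell), DNA replication (5 of 29 rose and 3 fell) and mitosis (3 of 25 fell). The same held for p53 targets (4 of 22 rose and 1 fell), NF-κB (3 of 13 fell), unfolded protein response (6 of 19 rose and 4 fell), and cholesterol synthesis (5 of 21 rose and 3 fell). It held also for ribosome biogenesis (3 of 20 fell), immediate-early genes (5 of 18 rose and 3 fell), ribosomal proteins (1 of 28 rose and 1 fell) and basal and mesenchymal genes (1 of 13 rose and 3 fell). Adjusted over the list alone, no count in these lists changed by more than 4. For mitosis, homologous recombination and cholesterol synthesis the median, mean and test did not share a sign. The balance of rises and falls depended on the scaling in several of these lists. With upper-quartile factors and with library sizes alone, end joining and ATM had 2 rises and 2 falls, and 1 and 2, and DNA replication had 5 and 5, and 5 and 7. The unfolded protein response had 4 and 5, and 4 and 6, immediate-early genes 3 and 4 with either, and cholesterol synthesis 4 and 4 with either. Mitosis had 2 rises and 2 falls with RLE size factors. The 3 NF-κB falls were all lost without either control ethanol or the second shBRCA1 ethanol library, and the 5 rises of end joining and ATM were 1 and 0 without the first and second control ethanol library and 0 and 2 without the first and second shBRCA1 ethanol library. Without either shBRCA1 E2 library mitosis had 4 rises and 5 falls, p53 targets 9 and 3, DNA replication 8 and 5 and ribosomal proteins 4 and 1. The 3 ribosome biogenesis falls were all lost without any 1 ethanol library, and the 3 DNA replication falls without either control ethanol library. Over the fits without 1 library, homologous recombination had 1 to 5 rises and 1 to 4 falls and immediate-early genes 2 to 7 and 1 to 4, so no direction can be read from these lists.

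In ethanol 3865 genes differed between shBRCA1 and control cells, or 18.8% of those tested, 2014 higher and 1851 lower. At least 2-fold changes were fewer upward, 86 genes, than downward, 415. The higher genes were 52.1% of all calls, but 39.6% with upper-quartile factors and 35.5% with library sizes alone. Fewer were called without any 1 ethanol library, and 5794 in a fit to the 2 groups compared only.

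The fourth comparison set shBRCA1 against control cells in E2. OAS2 stood at 11.3 ± 0.847 CPM in shBRCA1 cells and 323 ± 6.62 CPM in control cells (mean ± SD, n = 2; log2 fold change −4.84, SE 0.0805, edgeR adjusted p = 3.6e-17). IFI27 stood at 36.1 ± 0.766 against 555 ± 56.0 CPM (−3.94), TNFAIP3 at 35.7 ± 3.37 against 106 ± 1.98 CPM (−1.57) and NFKBIA (ENSG00000100906) at 297 ± 2.43 against 632 ± 8.71 CPM (−1.09). The 7 leading falls were IFI44L (ENSG00000137959; −5.96), IFI44 (−4.93), OAS2, IFNL3 (−4.81), XAF1 (−4.72), IFNL1 (−4.63) and BATF2 (−4.60), which are interferon-stimulated genes or, for IFNL1 and IFNL3, type III interferons. IFNL3 and IFNL2 are near-identical, so their counts may hold each other's reads. The leading rises were SLC26A2 (1.67), SCUBE2 (1.501), RPSAP47 (1.48), SCIN (1.46), CLSTN2 (1.46), CYP1A1 (1.45) and UGT2B15 (1.41). RPSAP47 is a ribosomal protein pseudogene and UGT2B15 has close paralogs, so their counts may hold reads of other genes.

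With E2, 27 of 28 interferon-stimulated genes fell in shBRCA1 cells (28 adjusted over the list alone; median log2 fold change −3.32, camera adjusted p = 1.86e-64). Hypoxia and glycolysis genes fell in 15 of 19 cases (17 adjusted over the list alone; camera adjusted p = 1.14e-20), with NDRG1 at −1.76 and PFKFB4 at −1.53, and NF-κB genes in 9 of 13 (11 adjusted over the list alone; camera adjusted p = 2.65e-13). Immediate-early genes fell in 15 of 18 cases and rose in 2 (16 and 2 adjusted over the list alone; camera adjusted p = 1.96e-09), JUNB at −0.92 and EGR1 at −0.56, with FOS (0.23) and FOSB (0.27) as the rising members. FOS lost its call without the first control E2 library (edgeR adjusted p = 0.0745), and FOSB without that library (0.0962) or the first shBRCA1 E2 library (0.0574). Cholesterol synthesis genes fell in 8 of 21 cases (11 adjusted over the list alone; camera adjusted p = 1.57e-04), STARD4 at −0.91, and in 4 without the first control E2 library. Estrogen-induced genes rose in 17 of 40 cases and fell in 10 (19 and 10 adjusted over the list alone; camera adjusted p = 8.00e-04), with CXCL12 (1.14) and AGR2 (0.91) rising and AREG (−0.90) and CA12 (−0.50) falling.

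The next 8 lists had more rising than falling genes in shBRCA1 cells with E2, with most members not called in 5 of them, and all 8 list calls were lost with an estimated correlation. Of 29 DNA replication genes 17 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 8.65e-08, adjusted p = 0.124 with an estimated correlation), DHFR at 0.65 and RRM2 at 0.52. Mitosis genes rose in 8 of 25 cases (9 adjusted over the list alone; camera adjusted p = 0.00257, adjusted p = 0.3998 with an estimated correlation, fry adjusted p = 0.0639), HMMR at 0.33. Homologous recombination genes rose in 7 of 26 cases, with BRCA1 as the only one that fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.195 with an estimated correlation), and FANCI had a log2 fold change of 0.35. End joining and ATM genes rose in 8 of 19 cases and fell in 1 (8 and 2 adjusted over the list alone; camera adjusted p = 0.00999, adjusted p = 0.197 with an estimated correlation), ATM at 0.44. R-loop genes rose in 6 of 22 cases (7 adjusted over the list alone; camera adjusted p = 0.00669, adjusted p = 0.121 with an estimated correlation). Ribosome biogenesis genes rose in 5 of 20 cases (5 adjusted over the list alone; camera adjusted p = 0.00334, adjusted p = 0.258 with an estimated correlation), NPM1 at 0.39, and ribosomal protein genes rose in 16 of 28 cases and fell in 3 (17 and 3 adjusted over the list alone; camera adjusted p = 5.55e-07, adjusted p = 0.378 with an estimated correlation, fry adjusted p = 0.0815). Of 13 genes encoded by the mitochondrial genome 11 rose (12 adjusted over the list alone; camera adjusted p = 1.13e-09, adjusted p = 0.114 with an estimated correlation), where the mitochondrial share was 6.52% and 7.59% against 5.45% and 5.34%. Without the second control E2 library 7 DNA replication and 9 ribosomal protein genes rose. Rising mitosis genes were 4 without either control E2 library, 5 without either control ethanol library, and 13 and 3 without the first and second shBRCA1 E2 library. Rising homologous recombination genes were 4 and 3 without the first and second control E2 library and 12 without the first shBRCA1 E2 library, and the fall of BRCA1 was lost without either control E2 library. Rising end joining and ATM genes were 3 and 5 without the first and second control E2 library and 5 without the second shBRCA1 E2 library. Rising R-loop genes were 3 without either control E2 library. Rising ribosome biogenesis genes were 2 without the second control E2 library, and 8 and 3 without the first and second shBRCA1 E2 library. Falling ribosomal protein genes were 0 without the first control E2 library and 1 without the second shBRCA1 E2 library.

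Luminal genes rose in 5 of 15 cases in shBRCA1 cells with E2 (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.138 with an estimated correlation), SPDEF at 0.54. Of 22 p53 targets 10 fell and 4 rose (10 and 4 adjusted over the list alone; camera adjusted p = 0.0341, adjusted p = 0.180 with an estimated correlation), BBC3 at −1.10 and GDF15 at −0.88 against ZMAT3 at 0.86, a call that was lost without the first control E2 library (0.0645). Unfolded protein response genes fell in 7 of 19 cases and rose in 3 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0169, adjusted p = 0.199 with an estimated correlation), and that call was lost without the first control E2 library (0.0596) or the first shBRCA1 E2 library (0.143), with 1 rising gene without the first control E2 library. Lists without a call were estrogen-repressed genes (4 of 15 rose and 6 fell), basal and mesenchymal genes (4 of 13 fell) and replication histones (3 of 11 rose, and 1 without either control E2 or the second shBRCA1 E2 library). Adjusted over the list alone, no count in these lists changed by more than 1. In all, 4371 genes differed with E2, or 21.2% of those tested, 1916 higher and 2455 lower, and 142 and 474 of them by at least 2-fold. Fewer were called without either control E2 library, and 3087 in a fit to the 2 groups compared only.

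**Figure D3:**
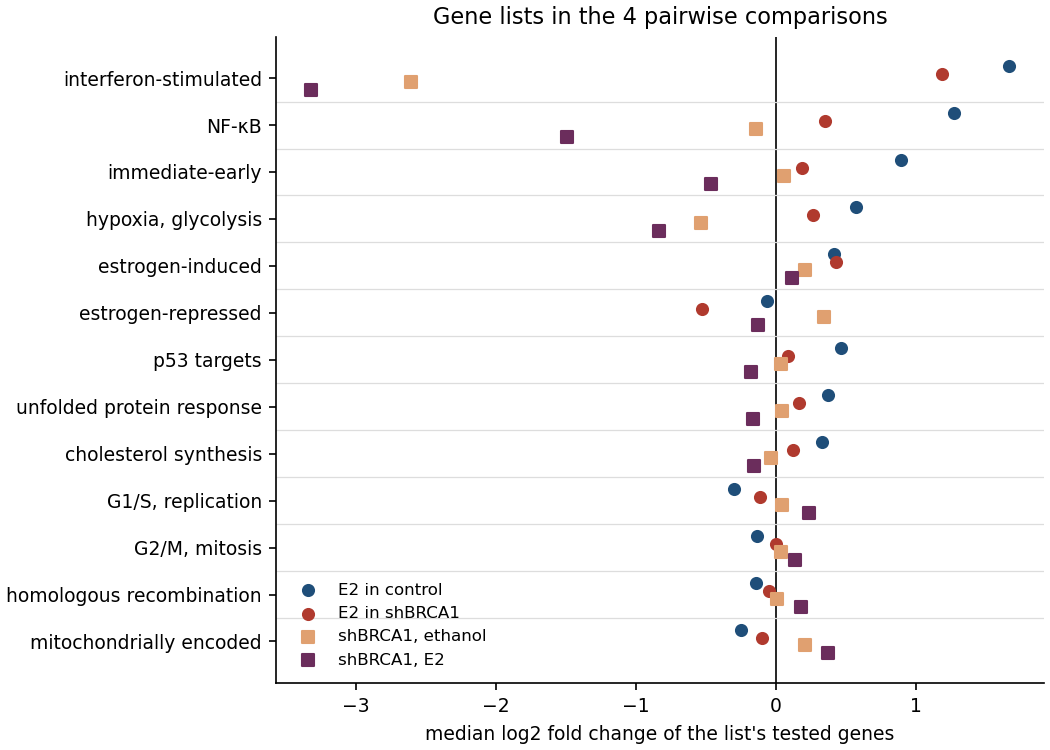
Median log2 fold change of 13 gene lists in the 4 pairwise comparisons. Interferon-stimulated genes had medians of 1.66 and 1.19 with E2 in control and shBRCA1 cells, and −2.61 and −3.32 for shBRCA1 against control cells in ethanol and E2.

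Across all 20592 genes the differences between shBRCA1 and control cells in ethanol and in E2, which share no library, correlated with a Pearson r of 0.293 and a Spearman rho of 0.356, and over the 6198 genes called in either with 0.565 and 0.680. In both treatments 897 genes were higher and 1083 lower in shBRCA1 cells, where independent lists would share 187.4 and 220.7, and 58 genes were called in opposite directions. The r across all genes was 0.639 with the filter of 1 CPM in 2 libraries, which keeps fewer genes, and 0.194 without the second control E2 library. Markers of other cell types changed in both directions with E2, whereas every called fibroblast and blood cell marker was lower in shBRCA1 than in control cells. Among 3 fibroblast markers COL5A1 rose with E2 in control cells (0.62) and COL3A1 (−1.33) and COL1A1 (−0.22) fell, and among 4 blood cell markers LCP1 rose (0.61). In shBRCA1 cells COL5A1 (0.40) rose with E2 and COL3A1 (−1.45) and COL1A1 (−0.34) fell. COL5A1 (−0.61) and COL1A1 (−0.34) were lower in shBRCA1 than in control cells in ethanol, as was the blood marker CORO1A (−0.38), and with E2 these stood at −0.83, −0.47 and −0.42, with 3 blood cell markers lower. Several of these calls were lost without 1 library. COL1A1 with E2 in control cells was lost without any 1 of the 4 control libraries (edgeR adjusted p from 0.0654 to 0.277), and COL5A1 with E2 in shBRCA1 cells without the second shBRCA1 ethanol library (0.227) or the first shBRCA1 E2 library (0.376). Between shBRCA1 and control cells, COL1A1 in ethanol was lost without the first control ethanol library (0.0588), CORO1A in ethanol without the second (0.0739), and LCP1 with E2 without the first control E2 library (0.0995). Neither of the 2 packaging-line markers tested, HOXA9 and CKMT1B, was called in any comparison.

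The fifth comparison tested whether the E2 effect itself differed between shBRCA1 and control cells. The rise of TNFAIP3 with E2 was smaller in shBRCA1 cells, at a log2 fold change of 0.40 against 2.15 in control cells (difference −1.76, SE 0.116, edgeR adjusted p = 1.2e-07), and that of NFKBIA was 0.26 against 1.21 (difference −0.95, SE 0.0809). OAS2 rose less too, 1.71 against 3.18 (difference −1.47, SE 0.117), whereas CASP14 rose more, 6.21 against 3.398 (difference 2.81, SE 0.234). CD36 (ENSG00000135218) went in opposite directions, 1.12 against −0.91 (difference 2.03, SE 0.138, edgeR adjusted p = 1.48e-07). GREB1, TFF1 and PGR were not among the genes with a called difference, and MYC was (difference −0.44, edgeR adjusted p = 0.00414).

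By list, the E2 effect was less positive in shBRCA1 cells for 9 of 13 NF-κB genes (9 adjusted over the list alone; median difference −1.20, camera adjusted p = 3.03e-16). The same held for 10 of 18 immediate-early genes (16 lower and 1 higher adjusted over the list alone; median −0.45, camera adjusted p = 2.33e-15), JUNB at −0.94 and ZFP36 at −0.74. It held as well for 17 of 28 interferon-stimulated genes (20 lower and 1 higher adjusted over the list alone; median −0.62, camera adjusted p = 7.99e-15). It held for 5 of 22 p53 targets (9 adjusted over the list alone; median −0.25, camera adjusted p = 4.67e-07), GDF15 at −0.71 and BTG2 at −0.75, and for 4 of 21 cholesterol synthesis genes (9 adjusted over the list alone; median −0.23, camera adjusted p = 3.24e-07), where INSIG1 (−0.47) was lost without the first control ethanol library (edgeR adjusted p = 0.0621). LDLR (−0.50) was lost without the second control ethanol (0.0679), second control E2 (0.0527) or first shBRCA1 ethanol library (0.0586). Of 19 hypoxia and glycolysis genes 8 had a less positive and 1, CA9, a more positive E2 effect (10 and 1 adjusted over the list alone; median −0.30, camera adjusted p = 9.69e-05), HK2 at −0.94. Of these genes CA9 rose from 1.14 to 4.77 CPM with E2 in shBRCA1 cells. Without 1 library, the less positive hypoxia and glycolysis genes were 3 without any 1 of the 4 control libraries or the first shBRCA1 ethanol library and 4 without the second. Immediate-early genes were 6 and 5 without the first and second control ethanol library, 6 without the second control E2 or the first shBRCA1 ethanol library and 16 without the first shBRCA1 E2 library. Cholesterol synthesis genes were 1 without either control ethanol, the second control E2 or the first shBRCA1 ethanol library, 2 without the second shBRCA1 ethanol library, and 10 and 7 without the first and second shBRCA1 E2 library. Interferon-stimulated genes were 10 without the second control E2 library and p53 targets 10 without the first shBRCA1 E2 library.

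Other lists had a called difference that was lost with an estimated correlation. They were estrogen-repressed genes, with 5 of 15 less positive (11 adjusted over the list alone; camera adjusted p = 3.14e-08, adjusted p = 0.0649 with an estimated correlation), EFNA1 at −0.95 and IGFBP3 at −1.57, and the unfolded protein response, with 4 of 19 less positive (4 adjusted over the list alone; camera adjusted p = 2.99e-05, adjusted p = 0.0649 with an estimated correlation), PPP1R15A at −1.02. DNA replication had 2 of 29 genes more positive (6 adjusted over the list alone; camera adjusted p = 1.3e-07, adjusted p = 0.111 with an estimated correlation), GINS2 (0.48) and CDC45 (0.48). With upper-quartile factors 5 genes of this list were called and with library sizes alone 3. GINS2 lost its call without either control ethanol, the second control E2 or the first shBRCA1 ethanol library. CDC45 lost it without any 1 ethanol or the second control E2 library. No single gene was called in the mitosis list (0 of 25; camera adjusted p = 1.38e-04, adjusted p = 0.311 with an estimated correlation, fry adjusted p = 0.112), homologous recombination (0 of 26; camera adjusted p = 0.00155, adjusted p = 0.111 with an estimated correlation) or the mitochondrially encoded genes (0 of 13; camera adjusted p = 0.00212, adjusted p = 0.311 with an estimated correlation, fry adjusted p = 0.267), and the same counts held adjusted over the list alone. Ribosome biogenesis had 1 of 20 genes more positive (2 adjusted over the list alone; camera adjusted p = 4.48e-04, adjusted p = 0.212 with an estimated correlation) and ribosomal proteins 1 of 28 (6 adjusted over the list alone, and 5 with upper-quartile factors or library sizes alone; camera adjusted p = 1.97e-06, adjusted p = 0.364 with an estimated correlation, fry adjusted p = 0.301), which was lost without the second control E2 library (0.0582). Estrogen-repressed genes with a less positive effect were 2 without either control ethanol or the first shBRCA1 ethanol library, 3 without the second control E2 library and 9 without the first shBRCA1 E2 library. Those of the unfolded protein response were 2 without the second control ethanol, second control E2 or second shBRCA1 ethanol library. Without the first shBRCA1 E2 library more positive effects were called for 9 genes of DNA replication, 4 of mitosis, 3 of homologous recombination, 8 encoded by mitochondria, 6 of ribosome biogenesis and 9 ribosomal protein genes. The single ribosome biogenesis call was lost without any 1 control or the first shBRCA1 ethanol library, and the single ribosomal protein call without any 1 ethanol or the second control E2 library.

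Lists without a called difference were estrogen-induced genes (6 of 40 less positive and 1 more positive, median −0.02, which turned to 0.04 with upper-quartile factors and 0.03 with library sizes alone), luminal genes (1 of 15 less positive) and basal and mesenchymal genes (1 of 13 less positive). No difference was called either for end joining and ATM (0 of 19), R-loop genes (0 of 22), replication histones (0 of 11), and fibroblast (0 of 3), blood cell (0 of 4) and packaging-line markers (0 of 2). Adjusted over the list alone, no count in these lists changed by more than 6. For basal and mesenchymal genes and replication histones the median, mean and test did not share a sign. Over the fits without 1 library, 4 to 13 estrogen-induced genes were less and 0 to 5 more positive, with 13 and 5 without the first shBRCA1 E2 library. Less positive luminal genes were 0 to 5, less positive basal and mesenchymal genes 0 to 1, and more positive end joining and ATM genes 0 to 4.

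The 7 leading genes with a less positive E2 effect were IFNL3 (−3.39), IFNL2 (−2.84), PSMB8 (ENSG00000204264; −2.60), GBP1 (−2.52), PSMB9 (ENSG00000240065; −2.16), BATF2 (−2.13) and THEMIS2 (−1.86). IFNL2 and IFNL3 are near-identical genes whose counts may hold each other's reads, so they may not be separate findings. The 7 with a more positive effect were KRT6A, SPRR1B, CASP14, CD36, S100A7 (1.504), the antisense transcript SLC16A4-AS1 (1.38), whose reads cannot be separated from its partner gene without a stated strand setting, and CA9 (1.36). KRT6A and SPRR1B had 3 counts or fewer in the shBRCA1 ethanol group, so their fitted differences are not bounds. With the shBRCA1 ethanol group set to the floor of 3 counts the difference of KRT6A was 2.57. Of these 14 genes IFNL3, BATF2, GBP1, THEMIS2, KRT6A, S100A7 and SPRR1B lost their calls without single libraries, which are listed below. PSMB8, PSMB9, IFNL2, CASP14, CD36, CA9 and SLC16A4-AS1 kept their calls.

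In all, 674 genes had a different E2 effect, or 3.27% of those tested, where DESeq2 called 1100 and edgeR without a count filter 1209. It was less positive in shBRCA1 cells for 543 and more positive for 131. Of the 543, 271 rose with E2 only among the calls of control cells, 125 rose in both kinds of cells, 42 rose in control and fell in shBRCA1 cells, 85 were called in shBRCA1 cells alone, as falls, 18 fell in both and 2 were called in neither. Of the 131, 66 were called in control cells alone, as falls, 29 in shBRCA1 cells alone, as rises, 19 rose in both, 10 fell in both, 6 fell in control and rose in shBRCA1 cells and 1 was called in neither. The genes with a more positive effect were 19.4% of the calls, but 40.4% with upper-quartile factors and 35.4% with library sizes alone. The number of calls was lower without any 1 control or shBRCA1 ethanol library and higher without either shBRCA1 E2 library. Each such fit leaves 1 library in a group, so fewer calls can come from lost replication and mark no library as unusual.

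**Figure D4:**
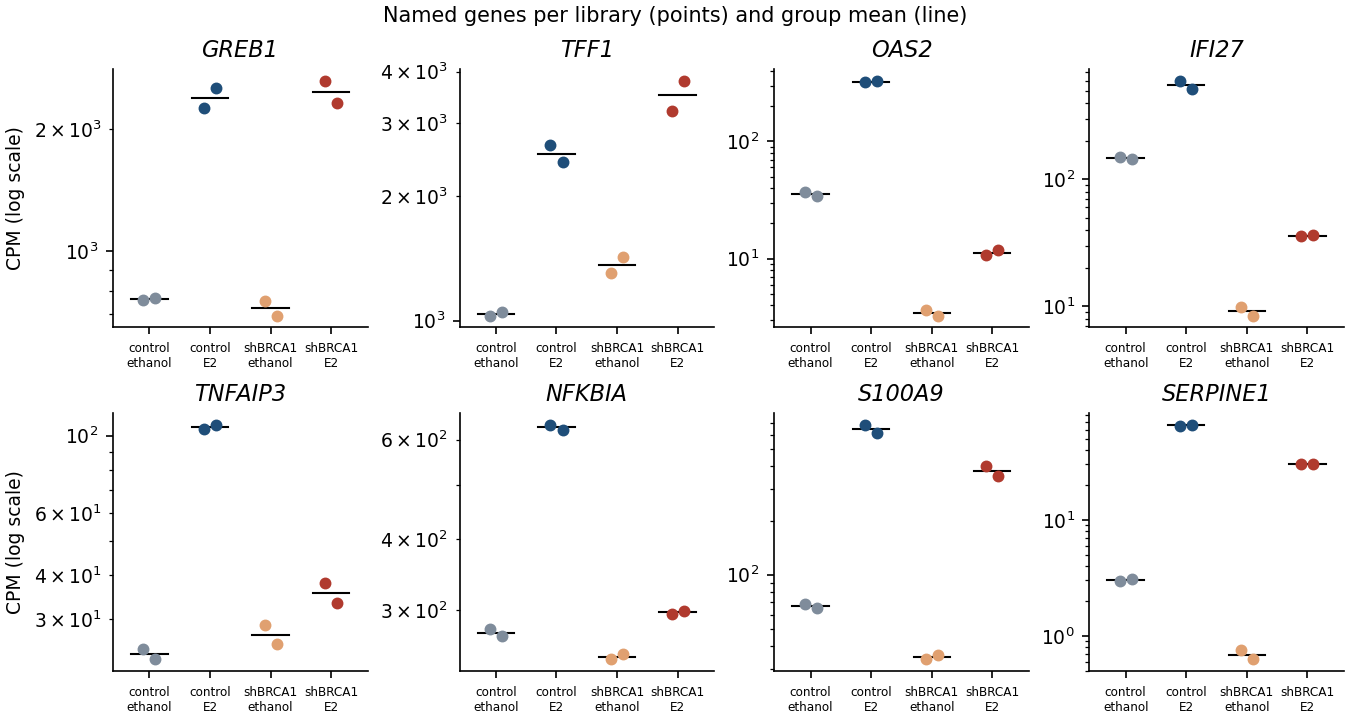
CPM of GREB1, TFF1, OAS2, IFI27, TNFAIP3, NFKBIA, S100A9 and SERPINE1 in each of the 8 libraries, on a log axis. GREB1 rose to 2387 and 2465 CPM with E2 in control and shBRCA1 cells, whereas OAS2 rose to 323 and 11.3 CPM.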

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

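The tests of whether E2 effects differed between shBRCA1 and control cells were planned, whereas the tests of explanations for the 3 patterns below were chosen after the results were seen. The E2 effect differed between the 2 kinds of cells for 674 genes. That number moved without any 1 library, as described above. Among the fixed lists the median difference of the E2 effect (shBRCA1 minus control, log2) was −0.46 for estrogen-repressed genes, 0.17 for DNA replication, 0.13 for mitosis, 0.13 for homologous recombination. It was −0.25 for p53 targets, −0.62 for interferon-stimulated genes, −1.20 for NF-κB genes and −0.20 for the unfolded protein response. Further medians were −0.23 for cholesterol synthesis, −0.30 for hypoxia and glycolysis, 0.11 for ribosome biogenesis, −0.45 for immediate-early genes, 0.14 for ribosomal proteins and 0.15 for mitochondrially encoded genes. With an estimated correlation 6 of the 14 calls were left: p53, interferon, NF-κB, cholesterol, hypoxia and immediate-early. The ribosomal protein call was also lost without the second control E2 library.

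Leaving aside genes named only for the lists chosen after the results were seen, the named genes with a less positive E2 effect in shBRCA1 cells that kept their call without any 1 library were ATF3 (−0.90), BTG2 (−0.75), CALCR (−0.79), CCNP (−0.93), EFNA1 (−0.95), EGR3 (−0.48), GADD45A (−0.89), GDF15 (−0.71), HK2 (−0.94), IFIT3 (−1.56), IFNL2 (−2.84), IGFBP3 (−1.57), JUNB (−0.94), KLF6 (−0.43), MYC (−0.44), NFKBIA (−0.95), NRIP1 (−0.62), OAS2 (−1.47), PPP1R15A (−1.02), PSMB8 (−2.60), PSMB9 (−2.16), SLC2A1 (−0.47), STC2 (−0.75), TNF (−1.62), TNFAIP3 (−1.76), VEGFA (−0.37) and ZFP36 (−0.74). Those among them with a more positive effect were CA9 (1.36), CASP14 (2.81), CD36 (2.03) and SLC16A4-AS1 (1.38).

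The rest of these named genes lost their call in a fit without 1 library, at the edgeR adjusted p given. They were ASCL1 (0.71; without the first control ethanol library 0.0715, the second control E2 library 0.0633), BATF2 (−2.13; second control E2 0.0538, second shBRCA1 ethanol 0.0732), CD44 (−0.44; first control ethanol 0.0613, second 0.0646) and CDC45 (0.48; first control ethanol 0.0605, second 0.119, second control E2 0.0902, first shBRCA1 ethanol 0.0635, second 0.0618). ELF3 (−0.49) was lost without the first control ethanol library (0.0756), the second (0.0555), the first control E2 library (0.0506) or the first shBRCA1 ethanol library (0.0610). GBP1 (−2.52) was lost without the second control ethanol (0.0527), first control E2 (0.0645) or second shBRCA1 ethanol library (0.274). GINS2 (0.48) was lost without the first (0.0642) or second (0.105) control ethanol, second control E2 (0.0909) or first shBRCA1 ethanol library (0.0866). IFNL3 (−3.39) was lost without the first control E2 (0.0719) or second shBRCA1 ethanol library (0.121). INSIG1 (−0.47) was lost without the first control ethanol library (0.0621) and KRT6A without the first (0.0538) or second (0.0529) shBRCA1 ethanol library. The fitted 6.13 of KRT6A rests on 0 counts in the shBRCA1 ethanol group and is no estimate of size, and with a floor of 3 counts there its difference was 2.57. LDLR (−0.50) was lost without the second control ethanol (0.0679), second control E2 (0.0527) or first shBRCA1 ethanol library (0.0586). RPLP0 (0.40) was lost without the first (0.197) or second (0.145) control ethanol, second control E2 (0.132), or first (0.189) or second (0.0582) shBRCA1 ethanol library. S100A7 (1.504) was lost without the second control ethanol library (0.0923). SPRR1B (2.84) was lost without the first (0.126) or second (0.145) control ethanol, first (0.0685) or second (0.0996) control E2, or second shBRCA1 ethanol library (0.253). TFF3 (0.54) was lost without the first (0.125) or second (0.0764) control ethanol, second control E2 (0.117), or first (0.0866) or second (0.0600) shBRCA1 ethanol library. THEMIS2 (−1.86) was lost without the first (0.182) or second (0.0856) control ethanol, first (0.169) or second (0.0932) control E2, or first (0.0902) or second (0.169) shBRCA1 ethanol library. UTP20 (0.47) was lost without the first (0.0683) or second (0.101) control ethanol, first (0.0601) or second (0.0588) control E2, or first shBRCA1 ethanol library (0.0958).

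The first pattern was the lower level of interferon-stimulated genes in shBRCA1 cells. Scaling of the libraries was argued against as the cause, since the list's median log2 fold change closest to 0 over 4 scalings and both treatments was −2.59. An unusual or mislabelled library was argued against too, since 28 of 28 genes had both shBRCA1 libraries below both control libraries in each treatment. Another difference between shBRCA1 and control cells than the BRCA1 level could not be told apart from BRCA1 itself, because there was 1 kind of BRCA1 shRNA cells. An effect of BRCA1 on interferon signaling stays an untested hypothesis.

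The second pattern was the rise of epidermal differentiation genes with E2. Keratinocytes mixed into the E2 samples were argued against by a sum of KRT5 and KRT14 of at most 1.42 CPM, beside 46.8 CPM of TP63 in control cells. This list was chosen after the results were seen, so its share of rises is no test of shared reads. The rise was not limited to the KRT6, S100A7 and SPRR families, as 11 of 13 other members rose in each kind of cells. The split of reads within these families stays open. A program of squamous differentiation under E2 stays an untested hypothesis.

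The third pattern was the smaller rise of NF-κB genes with E2 in shBRCA1 cells. A weaker E2 response of all induced genes was argued against by the median ratio of E2 effects, shBRCA1 over control. This ratio was 0.911 for the 28 estrogen-induced and 0.196 for the 10 NF-κB genes that rose in control cells, a choice that can lower it. A weakening shared by many other induced genes was not excluded, as this ratio was 0.337 for p53 targets, 0.350 for immediate-early, 0.403 for cholesterol synthesis, 0.466 for hypoxia and glycolysis, 0.507 for unfolded protein response and 0.586 for interferon-stimulated genes. A single unusual library was argued against by a median difference closest to 0 of −0.94 over the fits without 1 library, and a higher level before E2 by a median of −0.14 in ethanol, with 0 of 9 genes called higher in shBRCA1 cells (1 of 13 on the list without either shBRCA1 E2 library). A role of BRCA1 stays an untested hypothesis.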

How the results depend on the processing

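Stricter thresholds lowered the 5 numbers of called genes by construction. In the order tested they were 3035, 2170, 2110, 2502 and 286 at an adjusted p under 0.01. They were 966, 725, 501, 616 and 117 with a log2 fold change of at least 1. Without 1 library each, the same 5 numbers ran from 2718 to 5971, 2109 to 4687, 1668 to 5326, 2548 to 5789 and 256 to 2433. Fewer libraries leave fewer degrees of freedom, but the cause of the rises was not tested. Fits to the 2 groups compared only gave more calls without the shBRCA1 E2 group and fewer with it, so call numbers do not compare response sizes. The difference has no such check. The difference gave 1100 calls with DESeq2 and 1209 without a count filter, where 662 and 674 were shared, for causes that were not tested. List calls went from 51 to 23 and, for the difference, from 14 to 6 with an estimated correlation. The correlation of E2 effects was 0.765 with the CPM filter and 0.365 to 0.440 without 1 library, and that of the shBRCA1 effects 0.639 and 0.194 to 0.277. The CPM filter keeps fewer genes. BRCA1 with E2 ran from −0.33 to −0.22, with its lost calls given above. HOXA9 turned its sign without 1 library in control cells with E2 (−1.84 to 0.0655), in shBRCA1 cells with E2 (−6.12 to 0.11) and in the difference (−5.27 to 0.97), as did CKMT1B in ethanol (−0.0570 to 0.22), none of them called. The cause was not tested. The ribosomal protein list turned with E2 in control cells (camera adjusted p from 7.16e-06 to 0.745 without 1 library). A block for replicate number gave 4579, 3435, 3747, 4242 and 688 genes, and deviations of equal replicate numbers correlated between −0.0522 and 0.0424. With 2 libraries per group this cannot exclude a shared culture.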

Other observations

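These gene lists were chosen after the results were seen. Genes of the antigen presentation list all rose with E2 in control cells (16 of 16, median log2 fold change 1.38, camera adjusted p = 1.72e-24), TAP1 by 1.54 and IRF1 by 1.34. In shBRCA1 cells 2 of 16 rose and 1 fell with E2 (camera adjusted p = 0.638). The E2 effect was less positive for 14 of 16 (median −1.15, camera adjusted p = 7.75e-31), with IRF1 at −1.67 and TAP1 at −1.61. They were lower in shBRCA1 than in control cells for 13 of 16 genes in ethanol (median −1.19, camera adjusted p = 3.19e-15) and for 16 of 16 in E2 (median −2.29, camera adjusted p = 1.89e-33), where HLA-C had 89.3 against 419 CPM. HLA genes resemble each other, so the split of reads among them is uncertain. Among interferon ligands 4 of 4 rose with E2 in control cells, IFNL2 from 0.443 to 7.12 CPM, and 4 of 4 were lower in shBRCA1 cells with E2 (median −4.72). In ethanol 2 of 4 were lower (median −2.29, or −1.65 with bounds), and the E2 effect was less positive for 2 of 4 (median −3.07). Of the 2 calls in ethanol IFNL2 was lost without the second control ethanol library (0.107) or the second shBRCA1 ethanol library (0.0978). Of the 2 in the difference IFNL3 was lost without the first control E2 library (0.0719) or the second shBRCA1 ethanol library (0.121). IFNL2 and IFNL3 are near-identical and may hold each other's reads, so these counts are not of independent genes. In shBRCA1 cells 2 of 4 rose with E2, both in calls that were lost without single libraries. IFNL1 was lost without either shBRCA1 ethanol or the first shBRCA1 E2 library. IFNL2 was lost without either control E2, either shBRCA1 ethanol or the second shBRCA1 E2 library.

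Epidermal differentiation genes rose with E2 in 22 of 24 cases in control cells (median 4.802, camera adjusted p = 1.06e-25) and in 22 of 24 in shBRCA1 cells (median 6.03, or 5.62 with low-count members at their bounds; camera adjusted p = 1.05e-26). S100A9 went from 67.2 to 648 CPM in control and from 34.7 to 378 CPM in shBRCA1 cells. In ethanol 10 of 24 were lower and 1 higher in shBRCA1 cells (median −0.91, or −0.69 with bounds; camera adjusted p = 1.06e-04, adjusted p = 0.0695 with an estimated correlation), and in E2 11 were lower (median −0.48, camera adjusted p = 1.67e-06). The E2 effect was more positive for 6 and less positive for 1 of 24 (median 0.41, or 0.20 with low-count members at their bounds; camera adjusted p = 0.00849, adjusted p = 0.156 with an estimated correlation), KRT16 at 1.10. The less positive call was lost without either control ethanol, the first control E2 or either shBRCA1 ethanol library. Basal keratinocyte genes rose in 6 of 9 cases with E2 in control cells (camera adjusted p = 8.06e-08, adjusted p = 0.0609 with an estimated correlation) and in 6 of 9 in shBRCA1 cells (camera adjusted p = 1.16e-07, adjusted p = 0.0609 with an estimated correlation), COL17A1 by 3.21. With E2, 5 of these 9 were lower and 1 higher in shBRCA1 than in control cells (camera adjusted p = 0.00700, adjusted p = 0.222 with an estimated correlation), LAMB3 at −1.30. In ethanol 4 were lower and 2 higher (camera adjusted p = 0.171), with 2 lower and 0 higher without the second control ethanol library and 0 higher without the first control ethanol or first shBRCA1 ethanol library, and the difference between E2 effects was not called (1 of 9 less positive, camera adjusted p = 0.243).

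TGF-β target genes rose in 7 of 12 cases and fell in 1 with E2 in control cells (camera adjusted p = 5.35e-04), SERPINE1, a protease inhibitor, from 3.03 to 65.1 CPM. Without the second control E2 library 4 rose, and the fall was lost without that, the second control ethanol or the first control E2 library. In shBRCA1 cells 4 rose and 1 fell (camera adjusted p = 0.0677), SERPINE1 from 0.687 to 30.3 CPM. The difference between both E2 effects was not called for this list (1 of 12 more and 2 less positive, median −0.18, camera adjusted p = 0.0850), so its E2 response is not shown to differ. In E2, 6 of 12 were lower in shBRCA1 cells (median −0.41, camera adjusted p = 3.88e-05), TGFB1 at −0.96. In ethanol 4 were lower and 1 higher (camera adjusted p = 0.0492, adjusted p = 0.140 with an estimated correlation). Neuronal genes fell with E2 in 7 of 8 cases in control cells (median −1.89, camera adjusted p = 2.90e-11) and in 7 of 8 in shBRCA1 cells (median −1.56, camera adjusted p = 2.44e-11), PCDH10 from 66.0 to 14.4 CPM and from 54.7 to 12.7 CPM. The difference for this list was called (median 0.32, camera adjusted p = 0.0319) and lost at an adjusted p = 0.156 with an estimated correlation. Neither comparison of shBRCA1 with control cells was called for it, in ethanol (camera adjusted p = 0.312) or in E2 (camera adjusted p = 0.233). MHC class II genes were lower in shBRCA1 cells with E2 in 4 of 6 cases (median −2.36, camera adjusted p = 0.0187, adjusted p = 0.105 with an estimated correlation), CD74 from 2.47 to 0.464 CPM, at levels where few reads were counted. That count was 2 without either control E2 or either shBRCA1 E2 library. No other test of this list was called: not shBRCA1 against control cells in ethanol (camera adjusted p = 0.403), E2 in control cells (camera adjusted p = 0.933) or in shBRCA1 cells (camera adjusted p = 0.0677), nor the difference (camera adjusted p = 0.0836).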
